A study of Mus musculus with 8 samples.

How the data were processed

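MicroRNAs (miRNAs, short RNAs that repress messenger RNAs) were profiled in whole mouse hearts 21 days after ligation of the left anterior descending coronary artery, a surgical model of myocardial infarction (MI), or after a sham operation. There were 4 MI arrays and 4 sham arrays of 1 platform, the Affymetrix miRNA 4.0 array. Per the labels' protocols, total RNA was isolated, poly(A)-tailed and labelled with biotin. The titles also carry the suffix nc in both groups, which the labels do not explain. They number the sham hearts 1 to 4 and the MI hearts 1, 4, 5 and 7.

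The deposited values are log2 intensities that the authors produced with RMA, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of a probe set. Its version, the software that ran it and any detection calls are not given in the sources used here. The values ran from 0.617 to 15.9 in a single table that holds all 8 arrays, and they are not centred per probe set. Scanner files were not used here, so the background correction could not be varied. The precision is limited by the number of arrays.

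The table holds 3222 probe sets. By the form of their identifiers, 1908 carry miRBase accessions of mature miRNAs, 1255 carry accessions of hairpin precursors, and 59 are controls. The controls are 27 AFFX probe sets, 22 spike-in probe sets and 10 probe sets of another control transcript. The files do not pair these accessions with miRNA names, and 0 of the identifiers matched the table of mouse genes that was used for names. For this reason no miRNA is named, and at most 2 identifiers are printed in each direction. The 15 lists of miRNAs fixed before the data were examined (heart muscle, fibrosis, leukocyte, blood, endothelial, smooth muscle, low oxygen, off-heart tissues, and clusters and families, with 161 different members) could not be matched to rows. Neither the lists nor the planned comparison of the arms of a precursor, or of mature and hairpin probe sets, was tested. Among the mature probe sets, 16 repeated the values of another on all arrays, which leaves 1892 distinct profiles. Among the hairpin probe sets there were 1220.

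Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the log2 values of all 8 arrays, with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the 1908 mature probe sets, and separately over the 1255 hairpin probe sets, with a threshold of 0.05. No probe set was left out for a low level. Values measured once per array were compared with an exact two-sided permutation test over the 70 assignments of 8 arrays, whose smallest possible p is 0.0286. The spread between hearts was compared over the same assignments after the group mean of each probe set was subtracted, which makes that test approximate. The rule for printed probe sets was set in advance. It takes those past the threshold with the largest change, all MI values on one side of all sham values, and a level in the upper 50% of mature probe sets. Where fewer than 5 pass in a direction, it takes those with the smallest p.

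Without detection calls, a background level was taken from the 17 spike-in control probe sets that read near the floor of the scale, between 0.789 and 2.06 on any array. This criterion, the level bands and the mean level of 5 that divides dim from bright probe sets were chosen after seeing the data. A fold against a sham level under 2.06 is given as a lower bound with regard to the background only, with each sham value below 2.06 set to 2.06. It is taken from the group means and makes no allowance for the spread between hearts. The highest of these controls was read in sham heart 2.

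On simulated data with the means and spread of the 1908 mature probe sets, and 200 of the brightest 25% changed in each of 20 simulations, the limma fit recovered 12.2% of changes of 0.5 log2 units, 41.0% of changes of 1, 75.7% of changes of 2 and 93.1% of changes of 3. False calls made up 5.05% of all calls. These shares hold for this setting only. The values were drawn independently from normal distributions, and simulated falls could pass below the floor of the scale. With fewer true changes than 200 the adjustment is stricter, so recovery in the real data can be lower.

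The alternatives were restriction to the brightest 50% or 25% of probe sets, quantile normalization, centring on the brightest 25%, an intensity trend with a robust prior, array weights, the replicate number as a block, joint adjustment with the hairpins, an unmoderated test, and leaving out each array. A covariate for the bacterial hybridisation controls (15 bioB and bioC probe sets) and counting identical probe sets once were added after the data were seen. Only the numbers 1 and 4 occur in both groups. Deviations from the group mean correlated at -0.38 between the hearts numbered 1 and at -0.11 between those numbered 4, so the numbers were not treated as pairs.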

Results

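The study asked which miRNAs differ between mouse hearts 21 days after coronary artery ligation and sham-operated hearts. Male C57/BL6 mice were used, with 4 hearts per group and 1 array per heart. Most probe sets read near the floor of the scale. The median of the probe set means over the 8 arrays was 1.29 log2 units for mature miRNAs and 1.24 for hairpin precursors, and 271 of 1908 mature probe sets had a mean of 5 or more. The spike-in controls that read near the floor reached at most 2.06, and between 457 and 546 mature probe sets per array exceeded that value. Their mean number was 501 ± 50.8 (SD, n = 4) in sham hearts and 516 ± 17.8 (SD, n = 4) in MI hearts, which did not differ beyond the spread (exact two-sided permutation test, p = 0.543, adjusted p = 0.814 over 6 values compared per array).

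At 21 days after infarction, 10 mature miRNA probe sets were higher in MI hearts than in sham hearts, and 0 were lower (limma, Benjamini-Hochberg adjusted p from 0.000134 to 0.0390). The smallest fitted difference was 1.53 log2 units, a 2.88-fold rise, and the largest was 3.05, against a sham mean under the level of the dim controls. In all 10, every MI heart lay above every sham heart. The 10 probe sets were of 2 kinds by level. In sham hearts 7 were dim, with means from 1.36 to 3.89, and reached 4.03 to 5.91 in MI hearts. The other 3 were already bright in sham hearts, with means from 5.82 to 9.61, and reached 8.35 to 11.1. The sham means of 3 of the 10 did not exceed the 2.06 of the dim controls, while all 10 exceeded it in every MI heart.

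The largest fitted differences were those of MIMAT0004581_st and MIMAT0000381_st. The sham means of both lay under the level of the dim controls, so that their folds are given as lower bounds and their order among the 10 is not established. MIMAT0004581_st measured 1.92 ± 0.310 (SD, n = 4) log2 units in sham hearts and 4.97 ± 0.670 (SD, n = 4) in MI hearts, a difference of 3.05 with a standard error of 0.325 (limma, adjusted p = 0.00350). The rise amounts to at least 7.14-fold. MIMAT0000381_st measured 1.62 ± 0.262 (SD, n = 4) in sham hearts and 4.46 ± 0.189 (SD, n = 4) in MI hearts, a difference of 2.84 with a standard error of 0.154 (limma, adjusted p = 0.000134). On the same terms this is at least 5.28-fold. Its sham values lay between 1.28 and 1.83 and its MI values between 4.26 and 4.70.

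Among the 3 bright probe sets that rose, the one with the highest level went from 9.61 ± 0.365 (SD, n = 4) to 11.1 ± 0.265 (SD, n = 4), a rise of 1.53 (2.88-fold). The next by level went from 8.12 ± 0.208 (SD, n = 4) to 9.89 ± 0.314 (SD, n = 4), a rise of 1.77 (3.41-fold). The last went from 5.82 ± 0.473 (SD, n = 4) to 8.35 ± 0.525 (SD, n = 4), a rise of 2.53 (5.79-fold). A further 11 probe sets had an adjusted p between 0.05 and 0.1. All 11 had higher means in MI hearts, by 0.70 to 2.35 log2 units, with every MI heart above every sham heart. They include 1 pair with identical values on all arrays.

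**Figure D1:**
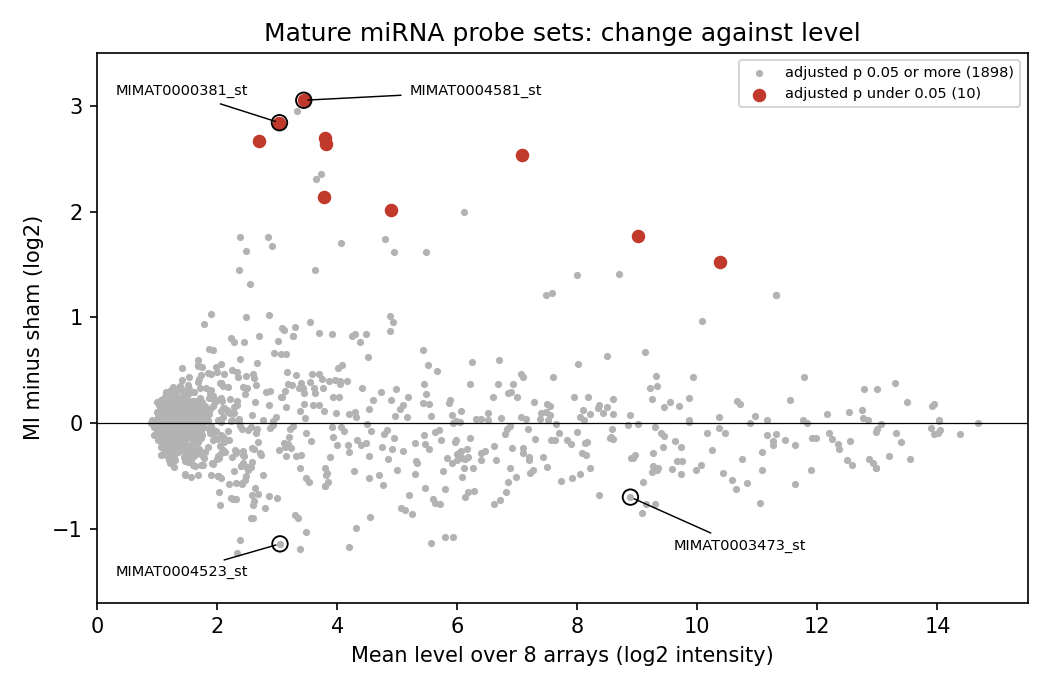
Each point is 1 of the 1908 mature miRNA probe sets, with its mean log2 intensity over the 8 arrays on the horizontal axis and the MI minus sham difference in log2 units on the vertical axis. The 10 probe sets past the threshold (red) all lie above 0, from 1.53 to 3.05, and the 4 circled and labelled probe sets are those given by identifier.

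With the deposited values of all 8 arrays, no mature probe set fell past the threshold in limma or in the unmoderated test. In limma 1 fell after quantile normalization, and 1 fell without sham heart 1. With all arrays, 61 had a lower mean in MI hearts at an unadjusted p under 0.05 in limma. The 5 falls with the smallest p in the upper 50% by level had adjusted p from 0.119 to 0.414 (limma), with differences from -0.56 to -1.23. The first of these, MIMAT0003473_st, measured 9.24 ± 0.200 (SD, n = 4) log2 units in sham hearts and 8.53 ± 0.231 (SD, n = 4) in MI hearts, a difference of -0.70 with a standard error of 0.147 (limma, adjusted p = 0.119). The next, MIMAT0004523_st, measured 3.62 ± 0.323 (SD, n = 4) and 2.47 ± 0.536 (SD, n = 4), a difference of -1.14 with a standard error of 0.278 (limma, adjusted p = 0.217). In both, every MI heart lay below every sham heart. The 5 brightest mature probe sets of sham hearts, at 14.0 to 14.7, differed between groups by -0.11 to 0.02 with standard errors of at most 0.128 (limma, smallest adjusted p = 0.933).

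**Figure D2:**
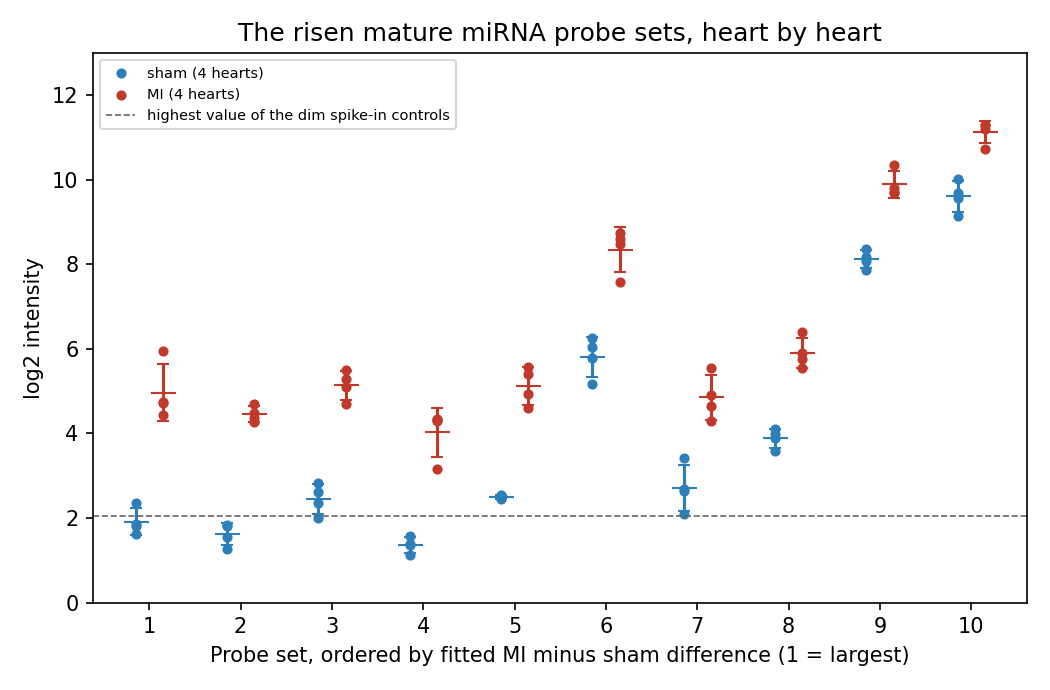
Log2 intensity of the 10 risen mature miRNA probe sets in each heart, ordered along the horizontal axis by the fitted difference, which sets no order among those with sham values under the dashed line. Points are single hearts (4 sham in blue, 4 MI in red), horizontal marks and bars are the mean ± SD, and the dashed line is the highest value of the dim spike-in controls, 2.06. In each of the 10, the 4 MI hearts lie above the 4 sham hearts.

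Over all 1908 mature probe sets, 55 had every MI heart above every sham heart and 24 had every MI heart below, where chance gives 27.3 in each direction. At an unadjusted p under 0.05, 59 were higher and 61 lower in MI hearts, 120 in all, against 95.4 from chance alone. Among the 271 probe sets with a mean of 5 or more, 13 were higher and 31 lower with the deposited values, where their median difference was -0.11, but 15 were higher and 12 lower after centring each array on the median of its brightest 25%. Quantile normalization gave 17 higher and 28 lower among 274. Among the 263 with means from 2 to under 5, 23 were higher and 13 lower with the deposited values. The centring moved the median of all probe sets from -0.0039 to 0.11 and the unadjusted split to 73 higher and 20 lower, which is 78.5% higher against 49.2% before. Under that scaling 25 mature probe sets rose past the threshold and 0 fell. Leaving out sham heart 3 raised the count from 10 to 17.

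The hairpin precursor probe sets showed no change past the threshold. Of 1255, 0 passed (limma, lowest adjusted p = 0.312) and 68 had an unadjusted p under 0.05, 40 higher and 28 lower in MI hearts, where chance gives 62.8. In 19 every MI heart lay above every sham heart and in 13 every MI heart lay below, against 17.9 from chance in each direction. Only 9 hairpin probe sets had a mean of 5 or more.

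Across mature probe sets, pairs of arrays correlated at 0.961 to 0.985 within the sham group, 0.980 to 0.987 within the MI group and 0.969 to 0.987 between groups. In the 477 brightest mature probe sets, the first principal component held 37.4% of the variance and did not separate the groups (exact permutation test, p = 0.457, adjusted p = 0.814). It ran from -11.7 in sham heart 1 to 16.5 in sham heart 3. The second component held 25.6%. It was 6.51 ± 3.01 (SD, n = 4) in sham hearts and -6.51 ± 4.05 (SD, n = 4) in MI hearts, with every sham heart above every MI heart (exact permutation test, p = 0.0286, the smallest these 8 arrays can give, adjusted p = 0.171). The spread between hearts did not differ detectably between groups. The SD was larger in MI hearts for 45.8% of mature probe sets, with a median SD of 0.185 in MI and 0.189 in sham hearts (permutation test on group-centred values, p = 0.343).

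**Figure D3:**
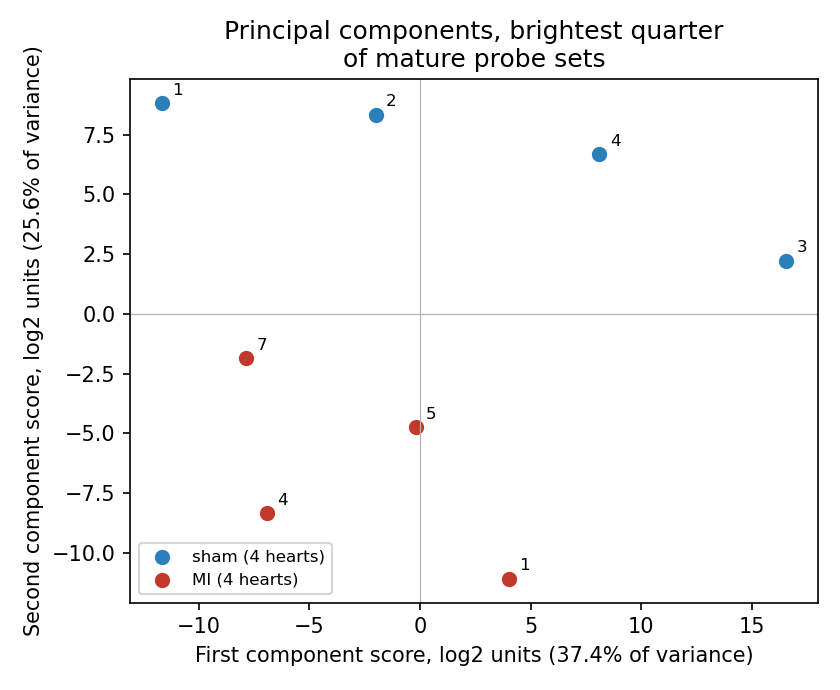
Scores of the 8 hearts on the first and second principal components of the 477 brightest mature probe sets, in log2 units, with replicate numbers beside the points. The sham hearts (blue) spread from -11.7 to 16.5 along the first component, and the groups separate along the second, on which the lowest sham heart is at 2.22 and the highest MI heart at -1.86.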

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

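The test on unadjusted directions among bright probe sets was added after the data were seen, with its criterion set before its own result. The tests of the hybridisation controls, of between-array normalization and of changes over 1 log2 unit were chosen or divided into parts after their results were seen. The test of the hybridisation controls replaced an earlier one that used their mean as a covariate, which decided nothing, since the 2 groups differed so little in that mean that the covariate could hardly have moved the rises.

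In 1 probe set, the value of 1 heart stood far from the others of its group. One of the risen probe sets, whose sham mean of 1.36 lay under the level of the dim controls, measured 3.16 log2 units in MI heart 4, while the other MI hearts lay between 4.29 and 4.35, a gap of 0.950 of the group's range. Of 36 groups of 4 values examined this way, 1 had such a value, while chance, at about 1 in 20, gives 1.8. No explanation was tested.

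Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, called as many as the 10 risen mature probe sets. The highest count in any other split was 0. The share of 1 in 35 is under the 0.05 set for this test, which argues against chance. It does not exclude chance, since 1 of 35 is the smallest share possible. The other splits also mix MI and sham hearts, so any real difference widens their spread and lowers their counts. The mean of the bacterial hybridisation controls was 0.049 log2 units higher in MI hearts (standard error 0.198), far under the smallest of the rises, 1.53. A hybridisation difference shared by a whole array would not single out 10 probe sets, whatever the controls read, so this comparison does not decide the question. Under the worse of quantile normalization and centring on bright probe sets, 9 of the 10 still passed, so most of the rises do not hang on the choice among these scalings. Both scalings started from values that RMA had already normalized, so an effect of that earlier step could not be tested. The infarction and any change in the cells that make up the heart remain open, since without miRNA names no cell type could be examined. A difference in the handling of the 2 groups was not tested and remains open too.

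The lack of falls is less firm. Over the same pair of scalings of the between-array normalization, 1 fall was called (by quantile normalization), so that the absence of falls may depend on the scaling. A floor that keeps dim probe sets from falling was tested on mature probe sets with a mean of 5 or more. Of the 44 with an unadjusted p under 0.05, 29.5% were rises (37.8% with quantile normalization), which shows no clear excess of rises where falls could be measured. The median difference of the bright probe sets was -0.11 with the deposited values and -0.06 with quantile normalization, which pulls these shares down. After centring on bright probe sets the share was 55.6%. That centring brings the median difference of the bright probe sets near 0 (0.0028), which pulls this share towards an even split. Over all mature probe sets 59 were higher and 61 lower at this threshold with the deposited values. That left no excess of rises for a floor to explain, so these shares do not decide on a floor. Of the bright probe sets that moved by over 1 log2 unit, 78.6% were rises (11 of 14, exact 95% interval 49.2% to 95.3%). The share was 86.7% (59.5% to 98.3%) with quantile normalization and 92.3% (64.0% to 99.8%) after the centring. The floor stays open for these larger changes, since the interval excludes 50% under both other scalings but not with the deposited values, and probe sets are not independent.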

How the results depend on the processing

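The count of mature probe sets past the threshold was 10 with the deposited values. It was 20 in the brightest 50%, 22 in the brightest 25%, 18 with an intensity trend and robust prior, 17 with array weights and 25 after centring on the brightest 25%, and in each of these the same 10 passed and 0 fell. Quantile normalization called 16, of which 15 rose, 1 fell and 9 were among the 10. The causes were not tested. Restriction tests fewer probe sets, but it also refits the variance information that limma shares across them, so the unadjusted p-values change too. The adjusted p of MIMAT0003473_st was 0.119 over all mature probe sets and 0.161 in the brightest 25% (limma). Leaving out each array gave 7 to 17, with the highest count without sham heart 3, the lowest without MI heart 7, and between 7 and 10 of the 10 passing. Without sham heart 1, 9 rose and 1 fell. With the replicate number as a block, 0 mature and 2 hairpin probe sets passed. Only 2 numbers are shared and 1 residual degree of freedom is left. The fitted rises of both printed risen probe sets stayed (3.36 and 3.07 log2 units), while their adjusted p was 0.787 and 0.546. The unmoderated test called 7, joint adjustment with the hairpins 10, the hybridisation covariate 13 and counting identical probe sets once 10. The hairpin count was 0 in the brightest 50%, with an intensity trend and robust prior, with quantile normalization and without each array in turn, and the remaining alternatives were not run on hairpins. The share of mature probe sets with the larger SD in MI ran from 42.3% to 52.9% when each array was left out, above 50% without sham heart 1 or 3, and no permutation test on group-centred values passed. The 4 printed probe sets kept their direction under every alternative that held them. The alternatives for the miRNA lists and for arms and precursors were not run, because the rows could not be named. Low signal limits what can be seen in the 1374 mature probe sets with a mean under 2.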

Other observations

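The test in this part was chosen after the result was seen. Along the first principal component of the bright mature probe sets, sham hearts 1 and 2 lay at the low end of their group and sham hearts 4 and 3 at the high end, and the same hearts had the lower and the higher values of the bacterial hybridisation controls. Over the 8 arrays, Pearson's r between component and control mean was 0.696 (exact permutation p = 0.0542) and Spearman's rho 0.619 (exact permutation p = 0.115). After centring within groups, r was 0.771 (permutation of the centred values over all 8 arrays, p = 0.0261, adjusted p = 0.0782 over 3 relations). This p is approximate, since values centred within groups are not freely exchangeable between groups. Without the 2 arrays farthest from the median control level, sham hearts 2 and 3, r was 0.569, and within groups of 4 hearts r was 0.930 in sham and -0.090 in MI. A candidate explanation for the spread is a hybridisation difference between arrays, which the centred value of 0.771 goes with, but the relation rests on the sham hearts and did not pass after adjustment. The sham hearts with the higher controls had fewer mature probe sets above the dim controls, 457 in hearts 3 and 4 against 546 and 544 in hearts 1 and 2. The MI hearts had 499 to 540. Other differences between arrays were not tested. The control mean itself was 11.4 ± 0.367 (SD, n = 4) in sham and 11.5 ± 0.147 (SD, n = 4) in MI hearts (exact permutation p = 0.857).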
